A study of Mus musculus with 12 samples.

How the data were processed

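Colon RNA was sequenced from 12 wild-type mice with chemically induced colitis, in 4 groups of 3 libraries. Colitis had been induced with trinitrobenzene sulfonic acid (TNBS) or with dextran sulfate sodium (DSS), and the mice had received thymopentin or normal saline. Groups and replicate numbers were taken from the treatment labels and the sample titles. The labels describe total RNA extracted with TRIzol and strand-specific TruSeq libraries. No colon library of a mouse without colitis was among the samples, and dose, timing, strain, sex and collection time are not given in the sources used here.

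Expression was deposited as FPKM, in which fragments are scaled to transcript length and to library size, for 55335 genes, with all 12 libraries side by side. The submitters' processing notes name FastQC, STAR 2.5, Cuffnorm, DESeq 1.22.1 and the genome build mm9, with no role or order. The gene models behind the values are not given in the sources used here. Of the gene identifiers 99.7% matched the names supplied with a later mouse build, and 86.6% of those carried the same symbol, so symbols are printed as deposited and no genomic position is given. The authors also deposited, per the file headers, a log2 fold change, a p-value and an FDR for selected genes of each model: 1173 genes for TNBS and 2326 for DSS. Each listed gene had a deposited p-value of at most 0.05 and a log2 fold change of at least 1 in size. In those tables the deposited per-library log2 columns carried no description. Raised back from log2, their low values were whole multiples of a single step per library, as a read count divided by a size factor would be. All 7326 low values, those of up to 30 reads, came out whole within 0.01 reads.

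Because the only table of all genes holds FPKM, which are not counts, each gene was tested on log2(FPKM + 1). Fold changes on this scale understate the change of genes with low FPKM. A count test was not run, since reads could be recovered only for genes the authors had already selected. Genes with a mean FPKM of at least 1 over the 12 libraries were kept, which left 13794; 21126 of the genes were listed at 0 in every library. limma 3.58.1 in R 4.3.3 fitted the 4 group means in 1 model with 8 residual degrees of freedom, with an empirical Bayes trend. Thymopentin was compared with saline within each model, the difference between these responses was tested as an interaction, and DSS saline was compared with TNBS saline. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. All limma p-values are two-sided. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so no such test was used. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the authors' tables, and matplotlib 3.10.9 drew the plots.

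A set of 34 gene lists (cell type markers, pathways and genes of neutrophil extracellular traps) was written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 4 tested genes, 31 in number, were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists. The same lists were tested with an estimated correlation and with fry, whose directional p tests whether the genes of a list move, on balance, one way. Within each list, p-values were also adjusted over the list alone. Genes named in the text are the 12 largest and 12 smallest fold changes among called genes whose libraries did not overlap between groups, leaving out unnamed gene models. To these were added up to 4 members of each called list by p, up to 4 members of both neutrophil lists, Padi4, Mpo, Elane and Camp always, the 5 smallest p of the difference, and up to 10 genes called in both models in 1 direction. The text gives a selection of the list members. Hoxb13, Reg3b, Fabp2, Ltf, Cd177, Ly6g, Nnt and the genes of the circadian clock were chosen after their values had been seen.

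The correlation of the 2 responses across genes was tested by exact enumeration of the 400 ways of labelling the libraries of both models, where the smallest p possible is 0.01. The replicate numbers are shared between saline and thymopentin groups, so deviations from the group means were correlated between libraries of the same number. In TNBS these correlations were 0.124, 0.268 and 0.476, all above 0.1, and the numbers were treated as pairing the libraries. TNBS saline 2 correlated slightly more with TNBS thymopentin 1, at 0.287, and no label says what a number stands for. The main fit holds no term for the pairs, so its TNBS values and counts are unpaired. The replicate block is given as an alternative. In DSS they were -0.136, 0.043 and -0.140, and the libraries were taken to share only a number.

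The total number of reads per library is not given in the sources used here. The step sizes gave size factors between 0.847 and 1.12, and the ratio of reads to FPKM put the libraries of each model at 0.848 to 1.09 of that model's mean depth. Genes listed by the authors at a mean near 1 FPKM were backed by a median of 88 reads per library in TNBS and 85.5 in DSS. The spread between libraries of a group was similar in all groups, with a median SD between 0.139 and 0.152 on the log2 scale.

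The pipeline was tested on simulated data with the mean of each gene over all libraries and its real spread. Noise was drawn independently for each gene. Shifted genes were drawn only from those with a mean log2(FPKM + 1) above log2(5). The shares below thus do not cover genes of lower FPKM, nor the correlation between genes in the real data. For the TNBS comparison, 38.8% of 67 genes shifted by 0.5 on the log2 scale were called, 79.1% of 67 shifted by 1, and 89.4% of 66 shifted by 2, with 2 false calls among 140. For DSS the shares were 37.3%, 77.6% and 97.0%, with 10 false calls among 151. Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or a mean FPKM of at least 5), quantile normalization, median-ratio rescaling, array weights, no trend, a replicate block, a separate fit per model, other thresholds, and leaving out each library in turn.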

Results

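Thymopentin, a synthetic pentapeptide made after the thymic protein thymopoietin, was tested in mouse colitis raised by TNBS, a hapten that provokes a T cell response, or by DSS, a polymer toxic to the colon epithelium. The series title puts the question to neutrophil extracellular traps, the webs of chromatin and granule proteins that neutrophils release. RNA from 12 colons was measured, 3 in each of the groups TNBS saline, TNBS thymopentin, DSS saline and DSS thymopentin. Summed FPKM lay between 384431 and 532510 per library, and between 13160 and 13805 genes reached 1 FPKM. Correlations between libraries of a group ranged from 0.932 to 0.977 across genes, against 0.933 to 0.968 between the groups of a model and 0.848 to 0.944 between models. The first principal component, with 49.3% of the variance, parted the models. The TNBS saline libraries differed among themselves, and TNBS saline 3 stood furthest from its group. It held 0.722 FPKM of Hoxb13, a homeobox gene of the distal colon, where TNBS saline 1 and 2 held 50.04 and 86.9. The same library had the most Reg3b, a bactericidal lectin (236 FPKM, against 113 and 1.47), and Fabp2, a fatty acid carrier of enterocytes (454 FPKM, against 275 and 46.7). For each of these genes TNBS saline 1 lay between TNBS saline 2 and 3, so the spread ran over the whole group.

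With thymopentin in TNBS colitis, genes of the interferon response fell. Oas3, an antiviral oligoadenylate synthetase, went from 5.66 ± 0.944 FPKM (SD, n = 3) with saline to 1.06 ± 0.0194 with thymopentin, a log2 fold change of -1.68 ± 0.20 (SE, limma adjusted p = 0.0064). Ifit1, which binds viral RNA, went from 21.5 ± 6.28 to 3.94 ± 0.348 FPKM, and Isg15, a ubiquitin-like modifier, from 34.3 ± 6.98 to 7.37 ± 1.54. Of 18 tested type I interferon response genes, 7 were called lower and 11 did not pass, with 16 lower when adjusted over the list alone. The list median was -1.12 (camera adjusted p = 3.81e-24), and this call was lost with an estimated correlation (adjusted p = 0.120 with an estimated correlation). By fry, which tests the list against no change and not against other genes, the adjusted p was 0.00904. Among 12 interferon gamma and Th1 genes, 3 were called lower and 9 were lower when adjusted over the list alone. These were Ido1, which degrades tryptophan, Cxcl9, which draws T cells, and the GTPase Gbp2, with log2 fold changes of -3.17 ± 0.34, -1.32 ± 0.21 and -1.11 ± 0.20. That list had a median of -1.05 (camera adjusted p = 1.55e-15), and its call was also lost (adjusted p = 0.120 with an estimated correlation). Outside the lists, the interferon-induced GTPases Iigp1, Igtp and Tgtp1 fell by 2.22, 1.95 and 1.67 on the log2 scale, and Gzma, a protease of cytotoxic granules, fell by 1.89. Leaving out 1 library ended the calls of Isg15 and Tgtp1 (TNBS thymopentin 1, adjusted p = 0.0565 and 0.0682) and of Cxcl9 (TNBS saline 1, thymopentin 1 or 3, up to 0.0875). Gzma lost its call without TNBS saline 1 or 2, any 1 TNBS thymopentin library, DSS saline 3 or DSS thymopentin 3 (up to 0.149), and Gbp2 without any 1 library except TNBS thymopentin 2 (up to 0.102). T cell markers lay on the same side: none of the 10 passed, over all genes or adjusted over the list alone, and their median was -0.37 (camera adjusted p = 0.000756; adjusted p = 0.478 with an estimated correlation). Without TNBS saline 2 the camera adjusted p of the T cell markers rose to 0.0547, the highest over its alternatives, which started at 1.08e-06. Their median was -0.20 without TNBS saline 2 or TNBS thymopentin 3, and -0.57 without TNBS saline 3. For the type I interferon list the camera adjusted p stayed between 4.62e-30 and 2.63e-15 over its alternatives.

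Of the mediators of inflammation, Nos2 and Tnf were called lower in TNBS colitis. Nos2, the inducible nitric oxide synthase, fell from 14.7 ± 2.0 to 6.13 ± 2.30 FPKM (log2 fold change -1.18 ± 0.19, limma adjusted p = 0.0212). Tnf, a central inflammatory cytokine, fell from 5.98 ± 1.09 to 2.18 ± 0.394 FPKM (adjusted p = 0.0461; 0.0916 with the replicate block). These were the 2 of 8 tested cytokines and mediators that passed, against 4 when adjusted over the list alone, and the list median was -0.31 (camera adjusted p = 0.000633; adjusted p = 0.201 with an estimated correlation and 0.0533 by fry), or -0.51 without TNBS thymopentin 3. Among 16 epithelial antimicrobial genes Nos2 alone passed, 5 were lower when adjusted over the list alone, and the median was -0.495 (adjusted p = 0.201 with an estimated correlation). That median was -0.78 without TNBS saline 3, the library with the most Reg3b, and -0.14 and -0.16 without TNBS saline 2 and TNBS thymopentin 3. Of 4 mast cell and eosinophil markers, Mcpt1, a protease of mucosal mast cells, fell by 1.62 on the log2 scale (adjusted p = 0.0341; 0.0815 with the replicate block). The list had 2 lower genes when adjusted over the list alone (adjusted p = 0.201 with an estimated correlation), and its call was lost without TNBS saline 2 or TNBS thymopentin 1 and under median-ratio rescaling. The call of Nos2 was lost without TNBS saline 2 or 3 or TNBS thymopentin 1 or 3 (adjusted p up to 0.0875), and that of Tnf without any 1 library except DSS thymopentin 1 and 2 (up to 0.151). Mcpt1 lost its call without any 1 TNBS library except thymopentin 2 and without any 1 DSS thymopentin library (up to 0.123). The 15 genes of fatty acid oxidation had a median of -0.11 with none passing by either adjustment (adjusted p = 0.633 with an estimated correlation); the median was -0.22 without TNBS saline 2 and 0.01 without TNBS saline 3, and the call was lost without TNBS saline 3 or TNBS thymopentin 2, under quantile normalization, with array weights and at a mean FPKM of at least 5.

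Neutrophil genes were scarce in these libraries. Padi4, the enzyme that citrullinates histones in extracellular traps, was listed between 0 and 0.0643 FPKM in the 12 libraries, and the granule proteins Mpo and Elane reached at most 0.0132 and 0.115 FPKM. Camp, the cathelicidin precursor, reached 0.731 FPKM in DSS saline and 0.0434 in TNBS, so none of these 4 genes passed the expression filter. S100a8 and S100a9, subunits of calprotectin, were measured at 2.24 ± 1.218 and 2.65 ± 1.76 FPKM in TNBS saline against 0.128 ± 0.119 and 0.314 ± 0.381 with thymopentin. They did not pass in TNBS (log2 fold changes -1.45 ± 0.31 and -1.36 ± 0.37; limma adjusted p = 0.0687 and 0.143). In the authors' deposited table for TNBS they had log2 fold changes of -3.98 and -3.26 with an FDR of 2.8e-05 and 0.0544, and Ltf (lactoferrin) one of -2.74 with an FDR of 0.260. Of 5 tested neutrophil markers none was called in TNBS, 2 were lower when adjusted over the list alone, and the median was -0.44 (camera adjusted p = 0.018; adjusted p = 0.378 with an estimated correlation). The 4 tested chemokines and growth factors that attract neutrophils had a median of -0.48, with none passing by either adjustment (camera adjusted p = 0.0235; adjusted p = 0.378 with an estimated correlation). The 7 tested granule and trap genes gave no call in TNBS (median -0.23, camera adjusted p = 0.134). Without TNBS saline 2 or TNBS thymopentin 3 the calls of the marker list and the chemokine list were lost, and the chemokine call also without TNBS thymopentin 2, under median-ratio rescaling and with array weights. The marker median was -1.02 without TNBS saline 3 and -0.82 without TNBS thymopentin 2, and the chemokine median -0.30 without TNBS saline 2 or TNBS thymopentin 3. Ly6g, the usual neutrophil surface marker, and Cd177 stood far above the other markers, Ly6g at a mean of 136 FPKM, and neither fell in both models. Ly6g went from 43.4 ± 36.8 to 69.5 ± 44.3 FPKM with thymopentin in TNBS and from 253 ± 57.0 to 178 ± 40.4 in DSS. Cd177 went from 110 ± 13.3 to 86.9 ± 43.1 FPKM in TNBS and from 30.9 ± 5.79 to 43.1 ± 4.35 in DSS. The value of Ly6g is uncertain because Ly6 family genes can share reads, which was not tested here. Whether Ly6g and Cd177 reads came from neutrophils was not tested either. Both were among the 5 tested neutrophil markers, so the medians of that list in both models include them.

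In DSS colitis S100a8 fell from 2.63 ± 1.40 to 0.105 ± 0.182 FPKM and S100a9 from 3.23 ± 0.886 to a level listed at 0 in all 3 thymopentin libraries (limma adjusted p = 0.00766 and 0.00689). The log2 fold change of S100a8 was -1.66 ± 0.31; none is given for S100a9, with 86, 45 and 72 reads in the saline libraries and 0 in each thymopentin library. Lcn2, which binds bacterial siderophores and is made by neutrophils and by inflamed epithelium, fell from 4.89 ± 1.60 to 1.07 ± 0.126 FPKM. In the authors' selected genes of DSS, S100a8 had a log2 fold change of -5.03 with an FDR of 0.0641, and S100a9 an FDR of 9.63e-10. The selected genes also held Camp, with a deposited log2 fold change of -3.41 and an FDR of 0.0158, from 17, 22 and 19 reads with saline and 7, 0 and 0 with thymopentin, and Ltf, with a log2 fold change of -4.06 and an FDR of 1.18e-20. Both lay below the expression filter. The responses of S100a8 and S100a9 did not differ detectably between the models (limma adjusted p of the difference 0.831 and 0.482). Relative to the median of all genes, which rose by 0.12 in DSS, the medians of neutrophil markers, granule and trap genes, and neutrophil-attracting chemokines were -0.62, -0.47 and -1.17. In these lists 2 of 5, 1 of 7 and 2 of 4 genes were called lower, and 2, 1 and 3 when adjusted over the list alone. Their calls were lost with an estimated correlation (adjusted p = 0.313 with an estimated correlation for the first pair of lists and 0.257 for the chemokines). Cxcl1 and Cxcl5, ligands of the neutrophil receptor Cxcr2, fell from 3.61 ± 2.68 to 0.476 ± 0.296 FPKM and from 4.39 ± 1.51 to 0.602 ± 0.289 FPKM. Both lost their call without DSS saline 1 or 3 or any 1 DSS thymopentin library, and Cxcl5 also without TNBS saline 1 or TNBS thymopentin 2 (adjusted p up to 0.096 and 0.134). The marker call was lost under quantile normalization, median-ratio rescaling and without TNBS thymopentin 2. Before the shift of all genes is taken off, the marker median went from -0.50 to -0.32 without DSS thymopentin 3, and that of the granule and trap genes from -0.35 to -0.23 without DSS thymopentin 1.

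**Figure D1:**
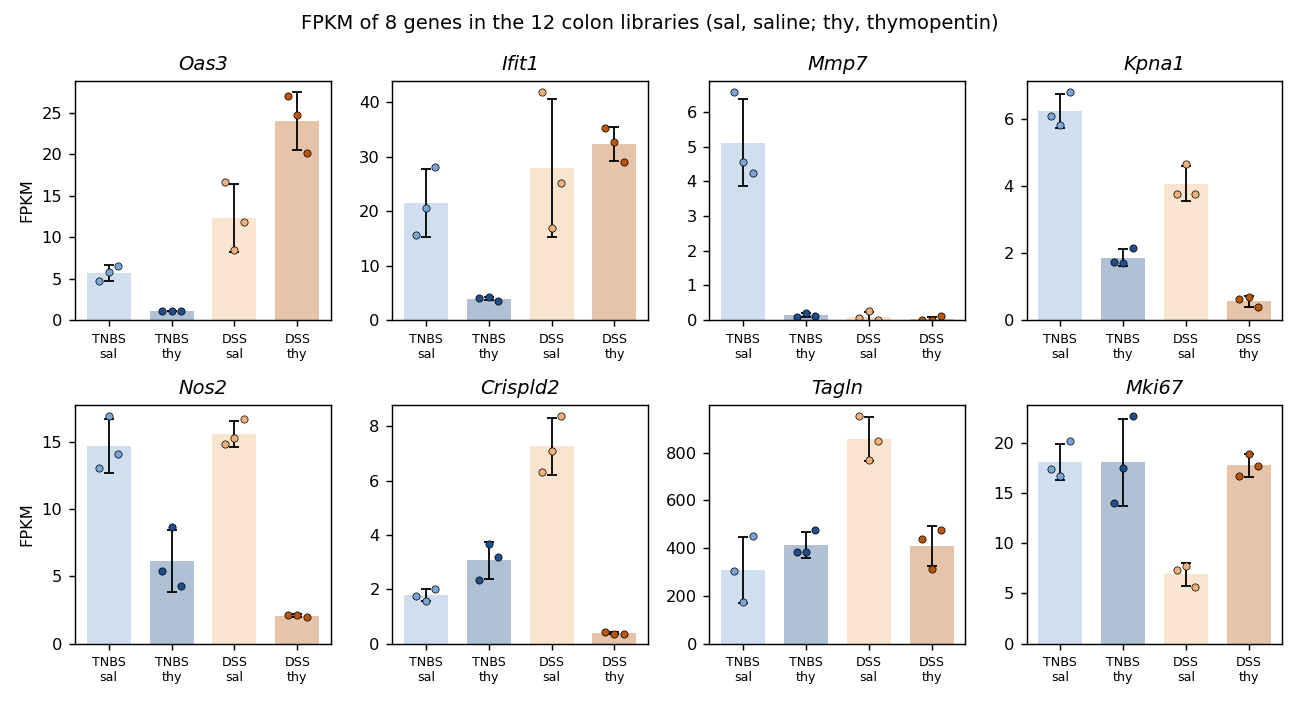
FPKM of 8 genes in each group; dots are the 3 libraries, bars their mean and error bars the SD. Oas3, Ifit1 and Mmp7 were lower with thymopentin in TNBS, Crispld2 and Tagln in DSS, and Kpna1 and Nos2 in both, while Mki67 was higher with thymopentin in DSS.

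Single genes with the largest falls in TNBS colitis included Mmp7, a matrix-degrading protease of epithelium, which went from 5.11 ± 1.26 to 0.137 ± 0.0628 FPKM (log2 fold change -2.41 ± 0.15, limma adjusted p = 0.000136). Among the authors' deposited genes its reads were 300, 180 and 202 with saline and 5, 9 and 5 with thymopentin. Mmp10, a further matrix protease, fell by 0.86 on the log2 scale (adjusted p = 0.0318; 0.0654 with the replicate block). Myl7, a myosin light chain named for the heart atrium, went from 15.2 ± 2.94 to 1.47 ± 1.16 FPKM. The immunoglobulin segment Ighv1-81 fell by 3.17 (adjusted p = 0.0307; 0.0552 with the replicate block) while Ighv1-52 rose by 1.61. Both are uncertain, since such segments share reads and mark single B cell clones. Among genes that rose were Igfbp6, a binder of insulin-like growth factor, from 1.43 ± 0.112 to 7.02 ± 1.30 FPKM (adjusted p = 0.00594), Clec3b (tetranectin) from 2.35 ± 0.678 to 7.30 ± 0.944, and Abi3bp, a matrix protein, from 0.966 ± 0.214 to 3.67 ± 0.700. Mfap4, of elastic fibres, and Gas1, a growth arrest protein, rose by 0.98 and 1.17 on the log2 scale (adjusted p = 0.0621 and 0.0503 with the replicate block). Of 17 matrix remodelling and fibrosis genes none was called higher and 2 lower, against 7 and 3 when adjusted over the list alone, and the list was not called (median 0.53, camera adjusted p = 0.163; adjusted p = 0.638 with an estimated correlation). Slc26a3, the chloride-bicarbonate exchanger of colonocytes, rose from 70.8 ± 4.27 to 174 ± 51.9 FPKM, the only one of 16 absorptive colonocyte markers to pass. Cyp2c69, a cytochrome P450, rose from 1.05 ± 0.0964 to 3.78 ± 0.588 FPKM, and Capsl and the transcription factor Pitx1 rose by 1.08 and 1.13 on the log2 scale. Without TNBS thymopentin 1 the calls of Mfap4 and Pitx1 were lost (adjusted p = 0.0819 and 0.0663), and without any 1 of the 3 TNBS saline libraries that of Slc26a3 (up to 0.0758). Mmp10 lost its call without any 1 TNBS library except saline 3, and without DSS saline 3 or thymopentin 3 (up to 0.123), and Gas1 without any 1 TNBS library or DSS saline 3 (up to 0.123). Capsl lost it without TNBS saline 1 or 2, TNBS thymopentin 1 or 3, or DSS saline 3 (up to 0.102). Ighv1-81 lost it without TNBS saline 1, any 1 TNBS thymopentin library, DSS saline 3 or DSS thymopentin 3 (up to 0.116), and Ighv1-52 without TNBS saline 1 or 3, TNBS thymopentin 2 or 3, DSS saline 3 or DSS thymopentin 2 (up to 0.113).

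Lists of muscle, nerve and related cells lay higher in TNBS with few members passing alone. No tested gene was called among 12 smooth muscle, 13 enteric neuron and glia, 10 enteroendocrine and 8 endothelial markers. Adjusted over the list alone, 5 neuron and glia markers and 2 enteroendocrine markers were higher, and none of the other 2 lists. Their medians were 0.51, 0.41, 0.30 and 0.27, with camera adjusted p of 0.018, 0.000226, 0.018 and 0.0215. The smooth muscle median was 0.83 without TNBS saline 3, 0.12 without TNBS saline 2 and 0.32 without TNBS thymopentin 3, and the neuron and glia median 0.27 without TNBS thymopentin 3. With an estimated correlation the calls were lost (adjusted p = 0.643, 0.378, 0.201 and 0.506 with an estimated correlation). The 15 genes of the BMP pathway had a median of 0.35 (camera adjusted p = 0.00121; adjusted p = 0.201 with an estimated correlation) and 4 were higher when adjusted over the list alone, against none over all genes; without TNBS saline 2 the median was 0.22. The 11 stem cell and Wnt target genes had a median of 0.30 with no gene passing by either adjustment (camera adjusted p = 0.0215; adjusted p = 0.442 with an estimated correlation). Without TNBS saline 2, 7 of the 15 TNBS list calls were lost, among them those of smooth muscle, enteroendocrine and endothelial markers; without TNBS thymopentin 3 it was 5, with smooth muscle, endothelial and stem cell lists. Without TNBS thymopentin 2 the enteroendocrine and stem cell calls were lost, and without TNBS saline 1 the endothelial and stem cell calls. The endothelial call was also lost under quantile normalization, and the enteroendocrine call with array weights.

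In all, 92 genes were called in TNBS colitis, 39 higher and 53 lower, and 44 of them changed at least 2-fold; 1748 had an unadjusted p under 0.05. The groups did not overlap in 18.8% of the genes, where chance gives 10%. Among the calls 42.4% were higher, a share that became 33.7% under quantile normalization and 31.6% under median-ratio rescaling. The authors' selected genes held 59 of the 92 calls (64.1%), and all 44 at 2-fold, each in the same direction. That table listed 677 genes as higher and 496 as lower (57.7% higher), the opposite balance to the calls here, and 362 of its genes were tested here. The balances are not like for like. The table was selected at an unadjusted p of at most 0.05 with at least a 2-fold change, the calls at an adjusted p with no fold requirement. At 2-fold on the scale used here the calls were still 10 higher and 34 lower. The expression filter differs too, the scaling may, and the cause was not tested. Leaving out 1 library changed the count most without TNBS thymopentin 1 (41 genes), TNBS thymopentin 3 (43), TNBS saline 1 (51), DSS saline 3 (57) and DSS thymopentin 3 (58), while 71 were called without TNBS saline 3. A fit of the TNBS libraries alone called 6 genes, 5 of them among the 92. Of 35 called genes followed by name, 12 kept their call whichever library was left out, among them Igfbp6, Clec3b, Abi3bp, Cyp2c69, Ido1, Iigp1, Ifit1, Igtp, Oas3 and Kpna1, and 19 lost it without TNBS thymopentin 1. Mmp7 kept its call in the leave-outs that tested it, but without TNBS saline 1 it lay below the expression filter. Over all alternatives only 4 of the 35 kept their call in each that tested them, Igfbp6, Mmp7, Oas3 and Kpna1. In the fit of the TNBS libraries alone the other 31 lost it, and with no filter 19 did.

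In DSS colitis the lists of muscle and nerve genes lay lower. Tagln, an actin-binding protein of smooth muscle, fell from 856 ± 93.0 FPKM with saline to 409 ± 85.0 with thymopentin (log2 fold change -1.08 ± 0.29, limma adjusted p = 0.0325), and Csrp1 and Lmod1, also of smooth muscle, fell by 1.03 and 0.91. Of 12 smooth muscle markers 6 were called lower, 9 when adjusted over the list alone, with a median of -1.06 relative to all genes. Of 13 enteric neuron and glia markers 11 were called lower, and all 13 when adjusted over the list alone, with a relative median of -0.78. Among them were Snap25, of synaptic vesicle release, from 4.94 ± 0.535 to 2.33 ± 0.668 FPKM, the neuronal tubulin Tubb3 and intermediate filament Prph, and the glial filament Gfap. The enteroendocrine list had 3 of 10 called lower by either adjustment, with Sst, the hormone somatostatin, falling from 25.7 ± 5.06 to 9.05 ± 2.83 FPKM. Scgn and Gcg (proglucagon) fell by 0.65 and 0.56. The endothelial list had 1 of 8 called, the junction protein Esam, against 2 when adjusted over the list alone, and the adipocyte list 1 of 6, against 4. Tubb3, Prph, Scgn and Esam lost their call without DSS saline 3, Scgn and Esam also without DSS thymopentin 2 or 3, and Gfap without DSS thymopentin 2 (adjusted p up to 0.0528, 0.0538, 0.0787, 0.0798 and 0.0598). Tagln lost it without DSS saline 1 or 3 or any 1 DSS thymopentin library (up to 0.111), and Csrp1 and Lmod1 without TNBS saline 1, any 1 DSS saline library, or DSS thymopentin 2 or 3 (up to 0.120 and 0.133). Lmod1 also lost it without TNBS thymopentin 1 or 2, and Gcg without TNBS saline 1 or 2, TNBS thymopentin 3 or any 1 DSS library (up to 0.143). Camera called all 5 lists, with adjusted p between 6.13e-11 for neurons and glia and 0.000284 for adipocytes. None held with an estimated correlation (adjusted p = 0.110 with an estimated correlation for neurons and for endocrine cells, and 0.313 for muscle, endothelium and fat). The share of FPKM on mitochondrial genes moved with the group, at 28.6 to 33.3% in DSS saline and 24.5 to 27.7% in DSS thymopentin. Hoxb13 of the distal colon was at 59.3 ± 6.33 and 111.8 ± 9.35 FPKM in these groups, which did not pass in the fit of all libraries (limma adjusted p = 0.606, with a range of 0.00965 to 0.735 over the alternatives). It did pass without TNBS saline 3 and in a fit of the DSS libraries alone.

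Genes of proliferation rose with thymopentin in DSS colitis. Mki67, a marker of dividing cells, rose from 6.89 ± 1.10 to 17.7 ± 1.13 FPKM (log2 fold change 1.26 ± 0.16, limma adjusted p = 0.00167), and Ccna2, Birc5 and Plk1, which act in the cell cycle and in mitosis, rose by 1.06, 0.98 and 0.71. Of 19 cell cycle genes 13 were called higher by either adjustment, with a median of 0.61 relative to all genes (camera adjusted p = 4.41e-06; adjusted p = 0.313 with an estimated correlation). Stem cell and Wnt target genes had 5 of 11 called higher, among them Axin2, from 0.792 ± 0.298 to 2.98 ± 0.561 FPKM, Ephb3 and Sox9. Adjusted over the list alone, 6 were higher and 1 lower, and the relative median was 0.41 (camera adjusted p = 0.022; adjusted p = 0.313 with an estimated correlation). This call was lost without DSS thymopentin 1 and with array weights. Genes of xenobiotic metabolism had 8 of 17 called higher, against 10 higher and 1 lower when adjusted over the list alone, with a relative median of 0.78 (camera adjusted p = 0.0063; adjusted p = 0.313 with an estimated correlation). The glutathione transferases Gstm1 and Gstm3 rose from 52.4 ± 8.66 to 137 ± 11.5 FPKM and from 5.11 ± 2.25 to 27.1 ± 1.93 FPKM. Cyp2s1 and Cyp2c55, both cytochromes P450, rose by 1.30 and 2.19 on the log2 scale; the call of Cyp2c55 (adjusted p = 0.0316) was lost with no filter and without DSS saline 1 or 3 or any 1 DSS thymopentin library, in a range of 0.00586 to 0.111 over its alternatives.

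Some inflammatory, antimicrobial and matrix genes fell in DSS colitis. Nos2 went from 15.6 ± 0.969 to 2.08 ± 0.0960 FPKM (log2 fold change -2.43 ± 0.19, limma adjusted p = 0.000119), and the inflammatory cytokines Tnf and Il1b fell from 7.51 ± 0.199 to 2.82 ± 1.21 FPKM and from 4.92 ± 2.0 to 1.202 ± 0.257 FPKM. The 8 cytokines and mediators had 3 called lower, 6 when adjusted over the list alone, and a relative median of -0.97 (camera adjusted p = 4.41e-06; adjusted p = 0.110 with an estimated correlation). Il22, a cytokine that acts on epithelium, went from 6.56 ± 6.13 to 0.0787 ± 0.136 FPKM, and Socs3, a feedback inhibitor of cytokine signals, from 33.4 ± 13.0 to 6.32 ± 1.79. Among 16 antimicrobial genes 6 were called lower by either adjustment, including Saa3, an acute-phase protein, and Duoxa2, a partner of an oxidase that makes hydrogen peroxide, with falls of 1.76 and 0.91. Of 17 matrix genes 4 were called lower by either adjustment, among them the proteins Fn1 (fibronectin) and Postn (periostin) and the protease Mmp10, which fell by 1.12, 0.65 and 1.19. The relative medians of these lists were -0.86 and -0.49, and both calls were lost (adjusted p = 0.110 with an estimated correlation). Macrophage markers had 3 of 15 called lower by either adjustment, the immunoglobulin receptor Fcgr1, the mannose receptor Mrc1 and the chemokine receptor Ccr2, with a relative median of -0.52 (adjusted p = 0.313 with an estimated correlation). Of 12 immediate early genes Ier3 alone was called by either adjustment, with a fall of 1.19, and the relative median was -0.85 (camera adjusted p = 2.5e-05; adjusted p = 0.313 with an estimated correlation). Interferon gamma and Th1 genes had none of 12 called by either adjustment and a relative median of -0.38 (camera adjusted p = 0.0116; adjusted p = 0.385 with an estimated correlation), and that call was lost without DSS saline 1 and at a mean FPKM of at least 5. Before the shift of all genes is taken off, the median of these genes went from -0.26 to -0.16 without DSS thymopentin 1, and that of the immediate early genes from -0.73 to -0.42 without DSS saline 1 and to -1.09 without DSS saline 2. Among single genes, Duoxa2 lost its call without DSS saline 3 (adjusted p = 0.0583), and Postn without DSS saline 1 or 3 or DSS thymopentin 2 or 3 (up to 0.0716). Il1b lost it without TNBS saline 1, TNBS thymopentin 1 or 2, DSS saline 1 or 3, or any 1 DSS thymopentin library (up to 0.116). Mrc1 lost it without TNBS saline 1, TNBS thymopentin 2, DSS saline 2 or 3, or any 1 DSS thymopentin library (up to 0.138), and Ccr2 without TNBS saline 1, TNBS thymopentin 1 or 2, or any 1 DSS library (up to 0.131).

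Further genes that rose in DSS colitis were Nxpe2 (neurexophilin and PC-esterase domain family), from 5.50 ± 0.943 to 52.2 ± 9.55 FPKM (limma adjusted p = 0.000944), Dbp, a clock-driven transcription factor, from 3.96 ± 1.92 to 25.2 ± 6.03, Pdzd7 and Tmem184b. Snord14e, a small nucleolar RNA, and Mir142hg, a microRNA host transcript, also rose, as did the immunoglobulin segments Igkv8-18, Igkv8-19, Igkv4-58 and Ighv1-69. These values are uncertain, because small RNAs lie inside other genes and such segments share reads; Igkv8-18 was listed at 0 in all 3 saline libraries. The largest falls included Clca4b, of the calcium-activated chloride channel regulators, from 201 ± 104 to 20.7 ± 8.70 FPKM, and Crispld2, a secreted protein, from 7.27 ± 1.04 to 0.392 ± 0.0375 (log2 fold change -2.56 ± 0.13, adjusted p = 2.43e-05). Trim15, Mfsd2a (a transporter of lysolipids), Lrg1, H6pd (an enzyme of sugar phosphate metabolism), Gem, Apol10a and Fabp6, a bile acid carrier, also fell, by 2.14 to 2.69 on the log2 scale. Clca4b and Igkv8-18 lost their call without DSS saline 3 or DSS thymopentin 3, and Igkv8-19 also without DSS saline 2 (adjusted p up to 0.072, 0.058 and 0.0785). Ighv1-69 lost it without DSS saline 1 or 3, and Igkv4-58 also without DSS thymopentin 2 or 3 (up to 0.0589 and 0.0741). Mir142hg lost it without DSS saline 2 or 3 or DSS thymopentin 2 or 3 (up to 0.0901). Snord14e and Apol10a lost it without any 1 of the DSS libraries, and Apol10a also without TNBS saline 1 or TNBS thymopentin 2 (up to 0.0823 and 0.116).

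In DSS colitis 2346 genes were called, 1753 higher and 593 lower, of which 319 changed at least 2-fold, 188 higher and 131 lower. An unadjusted p under 0.05 was seen in 4668 genes, and the groups did not overlap in 39.8%, where chance gives 10%. The share of higher calls, 74.7%, was 52.5% under quantile normalization and 49.8% under median-ratio rescaling, where the median of all genes moved from 0.12 to 0.02 and 0.01. The authors' selected genes held 596 of the 2346 calls (25.4%), and 298 of the 319 at 2-fold, all in the same direction. That table listed 872 genes as higher and 1454 as lower (37.5% higher), the opposite balance to the calls here, and 852 of its genes were tested here. The balances are not like for like. The table was selected at an unadjusted p of at most 0.05 with at least a 2-fold change, the calls at an adjusted p with no fold requirement. At 2-fold on the scale used here the calls were still 188 higher and 131 lower. The expression filter differs too, the scaling may, and the cause was not tested. Without DSS saline 3 the count was 916, and it was 1006 without DSS thymopentin 2, 1304 without DSS thymopentin 3 and 1351 without DSS saline 1. Of 74 called genes followed by name, 43 kept their call whichever library was left out, and 28 lost it without DSS saline 3. Il22 and Fcgr1 kept theirs in the leave-outs that tested them, but Il22 lay below the expression filter without DSS saline 1, and Fcgr1 without any 1 of the DSS saline libraries. In a fit of the DSS libraries alone 7 of the 74 lost their call, and with no filter 18 did.

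**Figure D2:**
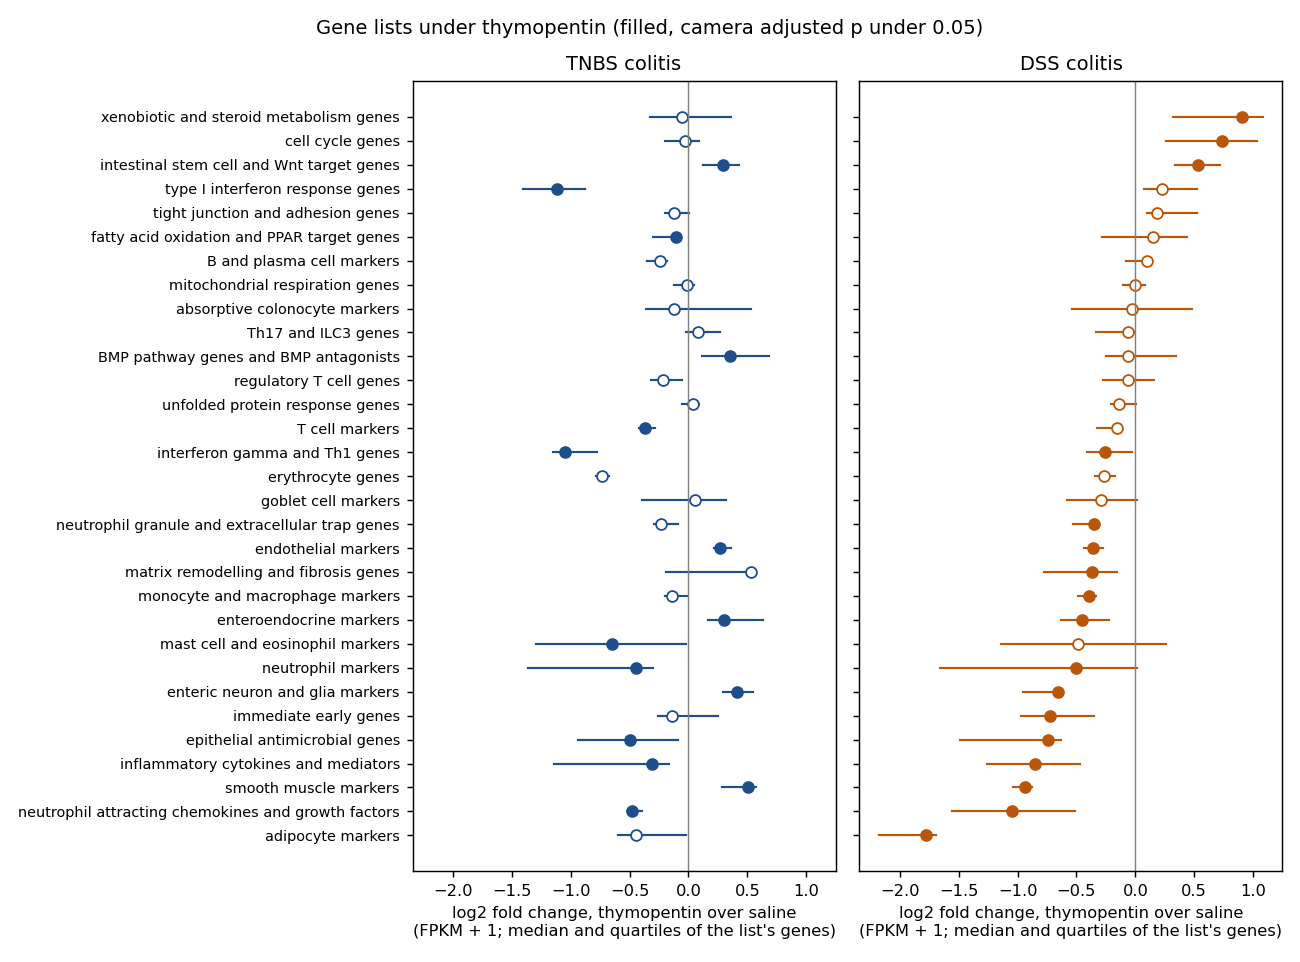
Median log2 fold change of each gene list with thymopentin in TNBS (left) and DSS (right), with lines from the lower to the upper quartile of its genes; filled dots mark a camera adjusted p under 0.05. Type I interferon genes lay at -1.12 in TNBS, and smooth muscle markers at 0.51 in TNBS and -0.94 in DSS.

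Some genes changed in 1 direction in both models. Kpna1, an importin that carries proteins into the nucleus, fell from 6.22 ± 0.506 to 1.86 ± 0.254 FPKM in TNBS and from 4.06 ± 0.517 to 0.563 ± 0.164 in DSS (log2 fold changes -1.34 ± 0.12 and -1.70 ± 0.12; limma adjusted p = 0.00178 and 6.86e-05). Nos2, Tnf, Mmp10 and Il4ra, a receptor chain for interleukins of type 2 immunity, were also called lower in both. Cpm, a carboxypeptidase, rose by 1.31 in TNBS and 1.46 in DSS, and Camk1d, a calcium-dependent kinase, by 0.81 and 0.90. Acsm3, an enzyme that activates fatty acids, rose by 0.95 and 1.44, Uxs1 by 0.67 and 0.70, and Cachd1 by 0.52 and 0.74, though in TNBS these 3 lost their call with the replicate block (adjusted p = 0.128, 0.114 and 0.115). Over all alternatives the adjusted p of the 9 TNBS genes that lost their call with the block lay between 0.000327 and 0.219. In TNBS the call of Cpm was lost without TNBS saline 1 (adjusted p = 0.0541), and that of Acsm3 without any 1 library except TNBS saline 2 (up to 0.18). Il4ra lost its TNBS call without any 1 TNBS library except thymopentin 2, and without DSS saline 3 or thymopentin 3 (up to 0.121). Uxs1 lost it without TNBS saline 1 or 2, TNBS thymopentin 1 or 2, DSS saline 3 or DSS thymopentin 3 (up to 0.123), and Cachd1 without TNBS saline 1 or 3, TNBS thymopentin 1 or 3, DSS saline 3 or DSS thymopentin 2 (up to 0.148). Of 35 genes called in both models, 24 went in the same direction, 12 higher and 12 lower, where independent lists would share 4.96 and 2.28. Another 6 were higher in TNBS and lower in DSS, against 1.68, and 5 lower in TNBS and higher in DSS, against 6.74. Both sets of calls rest on the same estimate of the spread of each gene, so they are not independent. The excess over these expected numbers is therefore no evidence of a shared response. Over all 13794 genes the responses correlated weakly (Pearson r = 0.104, exact permutation p = 0.31 over 400 labelings; Spearman rho = 0.075). This is a correlation across genes, which are not independent replicates. The labelings take no account of the TNBS replicate numbers, and no p over labelings that keep those pairs was computed.

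**Figure D3:**
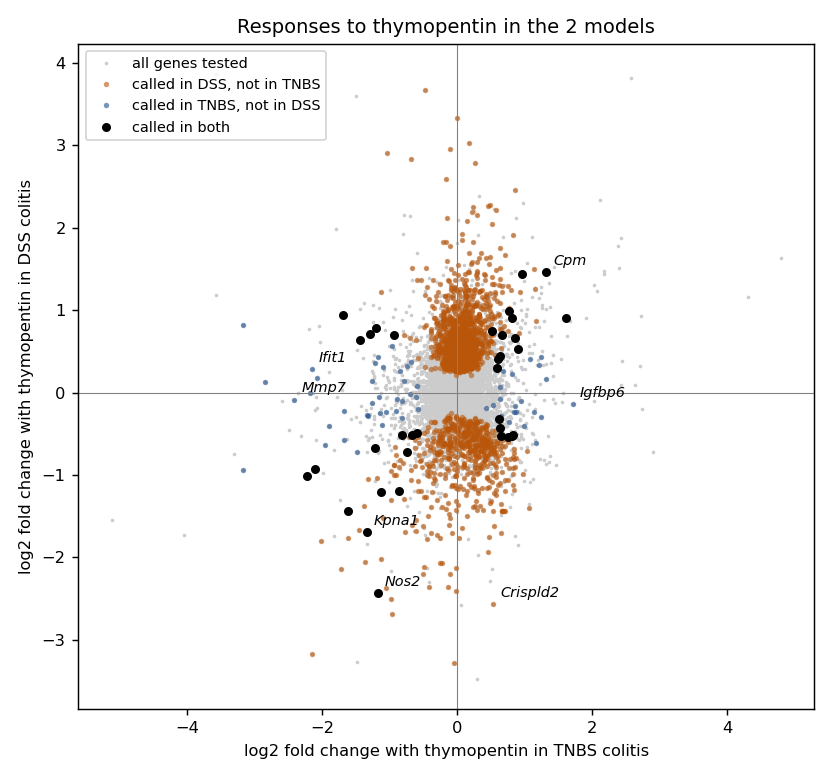
Log2 fold change with thymopentin in TNBS (x axis) against DSS (y axis) for the 13794 tested genes; colours mark genes called in each model, and black dots the 35 called in both. Kpna1 and Nos2 lay low in both models, and Crispld2 low in DSS, at a difference of -3.10 from TNBS.

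The response differed between the models for 710 genes, 376 with a more positive response in DSS and 334 with a more negative one; 3051 had an unadjusted p under 0.05. Crispld2 gave the smallest p, with a difference of -3.10 ± 0.19 (limma adjusted p = 0.00012), followed by Mmp7 at 2.32 ± 0.21, Acer1, a ceramidase, at 1.85 ± 0.18, Ncoa1, a nuclear receptor coactivator, at 1.223 ± 0.12, and Mgp, a calcification inhibitor of the matrix, at -1.98 ± 0.21. In DSS Mmp7 was near 0 in both groups (0.101 ± 0.135 and 0.0341 ± 0.0591 FPKM). Of 18 type I interferon genes 10 were called with a higher response in DSS, where Oas3 rose by 0.94 and the other 17 did not pass, and 15 when adjusted over the list alone. Among enteric neuron and glia markers 8 of 13 were called with a lower response in DSS, and all 13 when adjusted over the list alone. Of the 92 TNBS calls, 54 had a called difference, and 53 had the same sign in DSS. The share with a more positive response, 53.0%, was 41.1% under quantile normalization and 41.5% under median-ratio rescaling. The count was 177 without DSS saline 3, 213 without TNBS saline 1, 217 without DSS thymopentin 2, 355 without DSS thymopentin 3, 358 without TNBS thymopentin 1 and 388 without TNBS saline 2.

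Saline libraries of the models differed widely. Among single genes, Ccl5 and Ccl8, which draw T cells and monocytes, stood at 67.8 ± 4.72 and 88.9 ± 7.54 FPKM against 2.32 ± 0.576 and 3.08 ± 1.30 in TNBS, and Ccl21a, of lymphatic tissue, at 217 ± 28.9 against 12.3 ± 8.79 (limma adjusted p = 1.39e-06, 2.88e-05 and 0.000118). T cell markers had 9 of 10 called higher, including Cd3e and Cd3g of the T cell receptor complex, and macrophage markers 14 of 15, including Mrc1 and the complement gene C1qc, with the same counts when adjusted over the list alone. B and plasma cell markers were not called, with 1 of 13 higher and 1 lower by either adjustment (camera adjusted p = 0.159; adjusted p = 0.696 with an estimated correlation). Cell cycle genes had 18 of 19 called lower in DSS, against all 19 when adjusted over the list alone, with Ccna2 at 4.32 ± 0.786 against 16.2 ± 1.79 FPKM. Xenobiotic genes had 12 of 17 called lower, against 14, led by Cyp2c55 at 10.4 ± 8.41 against 720 ± 540. The antibody gene Ighg2c stood at 206 ± 51.1 FPKM in DSS saline and 0.218 ± 0.149 in TNBS saline. Ubd, an interferon-inducible modifier, S100g, a calcium-binding protein, and Fabp6 were higher in DSS by 3.83, 4.55 and 4.02 on the log2 scale, while B4galnt2 and B3gnt6, glycosyltransferases, and Prom1, a membrane protein, were lower by -4.13, -2.92 and -3.18; the call of B3gnt6 was lost without TNBS saline 1 or 3 (adjusted p up to 0.0585). Camera called 19 lists, 15 higher and 4 lower; none held with an estimated correlation (smallest adjusted p = 0.273 with an estimated correlation), while 4 had an unadjusted p under 0.05 there and fry called 21. A total of 6431 genes were called, 2090 higher and 4341 lower, a split of 32.5% higher that became 43.0% under quantile normalization and 44.8% under median-ratio rescaling. Model and any difference in batch, strain or date between the experiments coincide in this comparison.

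Camera called 15 of the 31 tested lists in TNBS and 17 in DSS, and none of these held with an estimated correlation, where 7 and 6 had an unadjusted p under 0.05. fry called 5 lists in TNBS and 13 in DSS. The lists of goblet cells, absorptive colonocytes, B and plasma cells, regulatory T cells, mitochondrial respiration, the unfolded protein response and erythrocytes were called in neither model. Erythrocyte genes had the lowest median among these, -0.74 in TNBS with none of 4 passing, and goblet cell markers were at 0.06 in TNBS and -0.29 in DSS. Tight junction and adhesion genes were not called by camera in either model (adjusted p = 0.0614 and 0.111), although 5 of 16 passed as higher in DSS and fry called the list there (adjusted p = 0.00441). Th17 and ILC3 genes were likewise called in DSS by fry (adjusted p = 0.0283), with Il22 the 1 gene of 6 to pass. Squamous epithelium, skeletal muscle and exocrine pancreas had too few expressed genes to be tested.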

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

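The comparisons of the interferon genes with macrophage and T cell markers, and of muscle, nerve, cell cycle and epithelial genes in DSS colitis, were chosen only after those results had been seen.

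The response to thymopentin differed between DSS and TNBS colitis for 710 genes by the interaction test. Single genes with the smallest p were Crispld2 (-3.10, DSS minus TNBS on the log2 scale), Mmp7 (2.32), Acer1 (1.85), Ncoa1 (1.223) and Mgp (-1.98). Mmp7 fell in TNBS and was near 0 FPKM in both DSS groups, where a fall could hardly show. Crispld2 and Mgp fell in DSS, and Acer1 and Ncoa1 rose there from 3.61 to 16.2 and from 1.42 to 5.08 FPKM. All 5 kept their call in each alternative that tested them. Crispld2, Mmp7 and Ncoa1 were not tested at a mean FPKM of at least 5, nor Mmp7 without TNBS saline 1. Over the 100 splits drawn 2 gave as many genes, the real one with 710 and 1 other with 1194. With all splits taken alike this share is under 0.05, which would exclude chance in the sense of no response in either model. The TNBS numbers were treated as pairing the libraries, however. Both splits are among the 37 drawn splits that part all 3 TNBS pairs, a share above 0.05. With the pairs kept, chance thus cannot be excluded for the count of genes. The split with 1194 swaps every DSS label and so measures the sum of the responses, which is a structure of the samples. These splits cannot test whether 2 real responses differ, since a response in DSS alone also raises the count. With the real DSS labels and TNBS saline 1, TNBS saline 3 and TNBS thymopentin 3 put together, 483 genes were called.

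Gene lists whose response differed by both camera and fry had median differences of 1.36 for type I interferon response genes, -0.38 for Th17 and ILC3 genes, 0.33 for tight junction and adhesion genes, and 0.80 for cell cycle genes. For matrix genes the median difference was -0.67, for xenobiotic metabolism 0.68, for enteric neurons and glia -1.06, for enteroendocrine cells -1.0 and for endothelium -0.67. With an estimated correlation the enteroendocrine list alone was called (adjusted p = 0.049), against 17 lists by camera at the preset correlation and 9 by fry. The Th17 call was lost without TNBS thymopentin 1 or DSS saline 1 (camera adjusted p up to 0.134 over its alternatives, from 0.00373), and the tight junction call without DSS saline 2 (up to 0.0812, from 0.00217). Chance cannot be excluded for the number of lists, since 10 of the 100 splits called as many as the 17 seen, and the highest other called 22.

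The fall of type I interferon genes in TNBS colitis was weighed first. Leaving out TNBS saline 3, the library with little Hoxb13, kept the list median at -1.06, and the scalings kept it at -1.11 or lower. This argues against that library alone and against scaling as the cause. Differences in Hoxb13 and similar genes among the other TNBS libraries were not tested as a cause. Against fewer macrophages in the thymopentin libraries, the list fell further than 15 macrophage markers. With a pseudocount of 0.1 the medians were -1.62 and -0.19, and the bootstrap interval of their difference ended at -0.84. This interval resamples the genes of each list and not the libraries, so it does not measure the spread between mice. The comparison was not repeated without TNBS saline 3. On log2(FPKM + 1), the macrophage median of the difference between models (DSS minus TNBS) went from -0.33 to -0.07 without that library. The small fall of the markers in TNBS may thus depend on it, and fewer macrophages are not excluded. Fewer T cells and a lower response per cell cannot be told apart. With a pseudocount of 0.1 the median of 10 T cell markers was -0.80, and the bootstrap interval of the difference from the list ended at -0.23. However, 8 of these markers had a group mean under 1 FPKM, too low to exclude a loss of T cells. An effect of thymopentin on the interferon response may underlie the pattern, with or without a change in T cells, and batch and collection day are not given in the sources used here.

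In DSS colitis the lists of muscle and nerve genes lay lower and that of cell cycle genes higher. Scaling was not the cause, as under both scalings the smooth muscle median was -0.99 or lower, against -0.94 as deposited, and the cell cycle median 0.64 or higher. A smaller share of muscle wall in the thymopentin libraries, which would lower muscle and nerve genes alike, stays open: the medians of these lists differed by -0.28, with an interval from -0.40 to 0.04. A larger share of epithelium as a whole would raise tight junction and adhesion genes as much as cell cycle genes. The cell cycle median lay 0.55 above that of tight junction and adhesion genes, with an interval from 0.01 to 0.84 that starts just above 0. This does not exclude a larger share of epithelium, since a larger share of its dividing cells alone was not tested. Both intervals resample genes and not libraries, so they leave out the spread between mice. The muscle and nerve part may thus reflect how much wall was sampled, and an effect of thymopentin on these tissues was not separated from it. Hoxb13 of the distal colon also differed between these groups, at 59.3 ± 6.33 FPKM with saline and 111.8 ± 9.35 with thymopentin. A difference in the colon position sampled was not tested as a cause of the muscle, nerve or cell cycle part.

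For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In TNBS colitis 92 genes were called and 19 in the highest other split, so 1 of the 10 splits gave as many; for lists the values were 15 and 18, with 3 of the 10 splits giving as many. Among the 3 other splits that part all 3 number pairs, at most 1 gene and 13 lists were called. In DSS colitis the real split called 2346 genes and 17 lists, and the highest other splits 2 genes and 15 lists (1 of the 10 splits in each case). Between the saline groups 6431 genes were called, against 2 in the highest other split (1 of the 10 splits). Other splits called a median of 12 lists in TNBS and 11 in DSS, so a number of camera calls is no evidence by itself.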

How the results depend on the processing

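Of the results for single genes named in the text, 1671 of 1938 values with 1 library left out and 1396 of 1520 under the other alternatives kept their direction and their side of the threshold. In the same order 258 and 108 were no longer called, 9 and 16 were newly called, and none changed direction. For lists 768 of 816 and 588 of 618 were kept. The list of fatty acid oxidation in TNBS reversed without TNBS saline 3, to a median of 0.0135 from -0.11, in a range from -0.22 over its leave-one-out values; the inflammatory cytokine list in the difference went from -0.30 to 0.000823 with no filter. The cause was not tested.

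The count of genes in TNBS was 92, with 44 under no filter, 2547 with array weights, 6 in a separate fit, 44 at 2-fold and 222 at an adjusted p under 0.1, and between 41 and 114 with 1 library left out. In DSS it was 2346, with 1447 at a mean FPKM of at least 5, 4025 with array weights, 319 at 2-fold and 3770 at 0.1, and 916 to 2524 with 1 library left out. The difference count was 710, with 355 under no filter, 385 at a mean of at least 5, 2889 with array weights, 335 at 2-fold and 1443 at 0.1, and 177 to 770. Between the saline groups it was 6431, with 3661 at a mean of at least 5 and 1439 at 2-fold. Stricter filters test fewer genes, and 2-fold and 0.1 move the threshold itself; for the others the cause was not tested. Array weights gave TNBS saline 1 a weight of 31.7, and their estimation stopped before it converged. Lists called in TNBS were 15, with 8 at a mean of at least 5, 0 by camera with an estimated correlation (7 unadjusted) and 5 by fry, and 10 to 18 with 1 library left out. In DSS they were 17, with 10 at a mean of at least 5, 0 with an estimated correlation (6 unadjusted, 13 by fry) and 16 to 20. The correlation of responses stayed between 0.0528 and 0.152.

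With the replicate block 79 genes were called in TNBS, 48 of them among the 92, and 1944 in DSS, 1616 of them among the 2346. Among the 35 called TNBS genes followed by name, 9 lost their call, with the values given beside them, and 26 kept it; the TNBS lists called without the block were all called with it. In DSS, where the numbers did not pair the libraries, 8 named genes lost their call with the block, at adjusted p of 0.0544 to 0.0939 (0.00466 to 0.143 over their alternatives).

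What depth limits was not tested. Near 1 FPKM a library held a median of 88 reads in TNBS and 85.5 in DSS. Padi4, Mpo, Elane, Camp and Ltf lay below the expression filter, Ltf with 156, 209 and 338 reads in DSS saline. Alternatives in which a gene fell under the filter gave no value for it.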

Other observations

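The comparison of the clock genes with a time of day was chosen only after the result was seen.

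In DSS colitis 5 of 7 output genes of the circadian clock were called higher: Dbp from 3.96 ± 1.92 to 25.2 ± 6.03 FPKM (limma adjusted p = 0.00206), Tef, Nr1d2, Per2 and Per3. Nfil3 and Npas2, which peak at the opposite phase, fell by 1.67 and 0.51 on the log2 scale, while Clock rose by 1.08. Per3 lost its call without DSS saline 3 or DSS thymopentin 2 (adjusted p up to 0.052), and Nfil3 without DSS saline 1 or 3 or DSS thymopentin 2 or 3 (up to 0.0569). Npas2 lost it without TNBS saline 1, TNBS thymopentin 1, DSS saline 1 or 3, or any 1 DSS thymopentin library (up to 0.129), and Tef without any 1 library except DSS saline 2 (up to 0.124). In TNBS none of the 7 was called by limma (Dbp 0.86, adjusted p = 0.314; Nr1d1 1.11, adjusted p = 0.257), though all 7 lay above 0, with a median of 0.59 against 1.04 in DSS. Among the authors' deposited genes for TNBS, Dbp had a log2 fold change of 1.39 with an FDR of 0.00816.

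Scaling was not the cause, since the lowest median of the output genes over models and scalings was 0.50. A different time of day at collection may shift such genes together and would lower the opposite-phase genes. The median of the 5 opposite-phase genes was -0.055 in TNBS, with 3 below 0, and -0.30 in DSS, with 4 below 0. The TNBS interval, from -0.61 to 0.18, resamples these genes and only runs from the lowest to the highest of them, so it decides nothing. A time of day and an effect of thymopentin thus cannot be told apart, and collection times are not given in the sources used here. No biological explanation was tested.

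Nnt, a mitochondrial transhydrogenase, varied between 0.183 and 5.002 FPKM over the 12 libraries, at 0.183, 1.54 and 5.002 within DSS thymopentin.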
